A study of Homo sapiens with 20 samples.

How the data were processed

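Single-cell RNA sequencing libraries of hEHT from H9 cells were analysed for 4 conditions: cryoinjured and non-cryoinjured tissue at day 2 and at day 4. The libraries were made with Chromium Single Cell 3' chemistry version 3.1, per the labels' protocols. The deposited values are UMI counts per gene and cell barcode made with Cell Ranger on GRCh37 (hg19), per the submitters' processing notes; its version is not given in the sources used here, and the matrix headers carry software version 3.1.0. All values were whole numbers of 0 or more, with 32738 genes under older symbols (CTGF for CCN2, CYR61 for CCN1). PECAM1, NEFL and UHRF1 are not among the gene names of the files. The labels list 4 samples per condition and the design text 3 biological replicates; the barcodes of each matrix share 1 suffix, so its cells could not be assigned to samples, and each matrix was treated as 1 pooled library. The digit of a library name was read as the day, the initial N as non-cryoinjured and the initial D as cryoinjured by elimination. A further matrix of hEHT after 3 days of culture was not used in any step, because its name gives no injury group.

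The libraries held 7579 barcodes and 142377622 UMIs (cryoinjured day 2), 8813 and 124789259 (non-cryoinjured day 2), 6033 and 111822307 (cryoinjured day 4) and 7279 and 141214326 (non-cryoinjured day 4). Cells were kept with at least 500 genes, at least 1000 UMIs and at most 25% mitochondrial UMIs. Over 25% mitochondrial UMIs were found in 21.7%, 28.9%, 32.6% and 20.4% of barcodes in that order, and 76.9%, 68.1%, 63.1% and 78.0% were kept. Median detected genes of kept cells were 4640, 4072, 4960 and 4713.5. Scrublet, as implemented in scanpy with exact neighbors and an expected rate of 0.06, called 22 of 21331 cells (0.103%) as doublets, far under the expected rate, so removal by the caller was nearly empty and removal of the top 6% of scores was added as an alternative. All 21309 kept cells were clustered together on 2000 variable genes, 30 principal components, 15 neighbors and Leiden resolution 0.6 with seed 1, which gave 17 clusters. With approximate neighbors in the doublet step 15 clusters had been found, so boundaries among collagen-rich cells are not stable. Software was Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9.

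Clusters were named from marker lists fixed before the data were examined; the thresholds of the naming rule were set after the clusters had been seen, and the rule was revised once. A cluster with a median UMI under 1/3 of that of all kept cells was called low-UMI. One with COL1A1 and COL3A1 of at least 2000 CPM was called collagen-rich, or mixed when TNNT2 also reached 1000 CPM. Any other took the list with at least 3 markers at least 2-fold above the remaining cells, provided that list led among the top 10 genes of at least 50 CPM, and otherwise stayed unnamed. The marker lists, of which a few members are not given here, were cardiomyocyte (TNNT2, TNNI1, TNNI3, TNNC1, MYH6, MYH7, MYL2, MYL3, MYL4, MYL7, ACTN2, ACTC1, TTN, RYR2, PLN, NPPA, NPPB, NKX2-5, CSRP3, MYBPC3); fibroblast (COL1A1, COL1A2, COL3A1, COL5A1, COL6A3, DCN, LUM, POSTN, PDGFRA, FBLN1, FBN1, MFAP4, MFAP5, OGN, TCF21, DPT, FAP, LOX, FN1, ELN); smooth muscle or pericyte (MYH11, CNN1, SMTN, LMOD1, ACTG2, RGS5, KCNJ8, ABCC9, CSPG4, NOTCH3, HIGD1B, PDGFRB, MCAM, DES, TAGLN, ACTA2); endothelial (PECAM1, CDH5, KDR, VWF, FLT1, TEK, TIE1, ESAM, EGFL7, CLDN5, ERG, EMCN, PLVAP, SOX17, RAMP2); epicardial or mesothelial (WT1, TBX18, UPK3B, UPK1B, ITLN1, BNC1, ALDH1A2, MSLN, KRT19, KRT8, KRT18, LRRN4, CALB2, TCF21); macrophage or other blood (PTPRC, CD68, CSF1R, CD14, LYZ, C1QA, C1QB, C1QC, AIF1, TYROBP, FCER1G, CD163, SPI1, LAPTM5, S100A8); erythroid (HBA1, HBA2, HBG1, HBG2, HBE1, HBZ, ALAS2, GATA1); endoderm or hepatic (AFP, ALB, TTR, APOA1, APOA2, APOB, SERPINA1, FOXA2, SOX17, EPCAM, CDH1, CLDN6, FGB, TF); surface or other epithelial (EPCAM, CDH1, KRT5, KRT14, KRT7, KRT8, KRT19, CLDN4, CLDN6, CLDN7, ESRP1, GRHL2, TP63); neural (SOX2, PAX6, TUBB3, STMN2, DCX, MAP2, ELAVL4, NEFL, NEFM, GAP43, NES); neural crest or glial (SOX10, FOXD3, ERBB3, S100B, TFAP2A, TFAP2B); pluripotent (POU5F1, NANOG, LIN28A, DPPA4, TDGF1, L1TD1, ZFP42, SOX2, DNMT3B); chondrogenic or skeletal (SOX9, ACAN, COL2A1, COL9A1, COL9A2, COL9A3, COL11A1, MATN4, MATN1, LECT1, RUNX2, SP7, IBSP); skeletal muscle (MYOD1, MYOG, MYF5, MYF6, PAX7, PAX3, DES, CHRNA1, MYH3, MYH8, ACTA1, TNNI2, TNNT3).

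UMIs were summed over the cells of a library, over all kept cells and within each cluster or class with at least 100 cells in every library, which gave 11 compared units. CPM carry exact Poisson 95% intervals and shares exact binomial 95% intervals, and both cover counting error only. Log2 ratios used a pseudocount of 1 CPM, which the intervals of CPM do not hold. With 1 library per condition no test, p-value or count of changed genes was made from cells; the fixed rule of 1.5-fold sorted genes. The planned model per sample was not run because cells could not be assigned to samples. Genes were named by a rule fixed before the data were examined. Per unit and day it took the 6 highest and 6 lowest log2 ratios among genes with a mean of at least 50 CPM. Left out were mitochondrial and ribosomal protein genes, XIST, genes of the Y chromosome, clone-named genes and genes under 1/10 of their CPM in another class. TNNT2, COL1A1, COL1A2, COL3A1, POSTN, ACTA2, FN1, CTGF, NPPA, NPPB, MYH6 and MYH7 were always given, and from each list the 2 members with the largest ratio and the 2 with the highest level. The counting intervals of the paired CPM did not overlap for any gene named by rank. Not every gene that met these rules is given in the report. Genes named by rank whose UMIs came mostly from 1 or a few cells are named with that fact, which was not examined for the genes always given or taken from lists.

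The gene lists, fixed before the data were examined, were fibrillar and network collagens; non-collagen matrix; matrix remodelling; TGF-beta response; myofibroblast contractile; YAP and SRF targets; sarcomere; calcium handling and ion channels; fetal and stretch-stress cardiac genes; cardiac transcription factors; hypoxia and glycolysis; oxidative phosphorylation and fatty acid oxidation; cell cycle; p53, growth arrest and apoptosis; heat shock and protein folding; unfolded protein response; immediate early and dissociation genes; inflammation and chemokines; interferon response; Wnt and BMP pathway; growth factors and angiogenesis; epicardial activation and EMT; lipid and cholesterol; metallothionein, iron and oxidative stress. Each was described by the median log2 ratio of members with a mean of at least 5 CPM, its members 1.5-fold higher or lower, and the percentile of its median among 10000 random lists of the same size, drawn with replacement within 20 bins of mean CPM. The percentile describes these libraries and is no test. Lists of cytosolic and mitochondrial aminoacyl-tRNA synthetases were written after the named genes had been seen. The share of squared log2 differences due to the injury by day contrast was taken over the 4 libraries.

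The ratio and list steps were tested on simulated data, Poisson draws from the pooled profile of a pair of libraries with 200 genes given a known difference. Of genes given a 2-fold or 4-fold difference 100% were recovered, and 0% of unchanged genes passed 1.5-fold. The draws held counting error only, without variation between cells, tissues or libraries. These rates therefore check the calculation and do not show how often unreplicated libraries differ by 1.5-fold. Over all kept cells the intervals held the true CPM ratio for 95.6% of genes at day 2 and 94.6% at day 4, and the fold put in for 74.8% and 89.6%, since spiked genes shift the totals. In cardiomyocyte-like cells the intervals held the true ratio for 95.1% and 95.0% of genes. Random null lists fell outside the central 95% in 4% and 4.5% of cases over all kept cells and 7% and 3.5% in cardiomyocyte-like cells.

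Alternatives fixed before the data were examined were mitochondrial limits of 10% and none, a minimum of 1000 genes, no doublet removal, resolutions of 0.3 and 1.0, clusters made within each library, 4000 variable genes, CPM without mitochondrial and ribosomal protein genes, median-ratio scaling, list minimums of 20 CPM and none, a pseudocount of 5 CPM, the mean of each cell's CPM, and thinning of each cell to 3000 UMIs. Removal of the top 6% of doublet scores and counting low-UMI cardiomyocyte clusters as cardiomyocyte-like were added after the data had been seen. The values followed through the alternatives were chosen after the medians were known. A value was counted as unmoved when it stayed within the spread of the main value: binomial limits for shares, 2000 resamples of list members, 1000 resamples of genes for correlations, and the exact ratio interval for genes.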

Results

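Human engineered heart tissues (hEHT) built from H9 cells were profiled by single-cell RNA sequencing with and without cryoinjury, at day 2 and at day 4. Each condition was 1 pooled library, and the 4 samples listed per condition could not be told apart among its cells. Every comparison was therefore 1 library beside 1 library, nothing was tested, and the 95% intervals in brackets cover counting error only. Which library held the cryoinjured tissues was read from the letters of the library names, so every direction of injury given here rests on that reading. The filters kept 5825 cryoinjured and 6001 non-cryoinjured cells at day 2 and 3809 and 5674 at day 4. Their median UMIs were 21197, 17466, 24933 and 21733 in the same order. Levels are CPM, UMIs summed over cells and scaled to the summed total, with the cryoinjured value first in each pair, and ratios are log2 of cryoinjured over non-cryoinjured. A gene was called higher or lower when the ratio reached 1.5-fold.

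Collagen-producing cells filled most of the tissues, and they fell into several states. Clusters 0 to 5 and the small cluster 16 each held COL1A1 and COL3A1 above 2000 CPM, with COL1A1 8122 and COL3A1 6134 CPM in cluster 3, LUM 4432 CPM in cluster 0 and DCN 3144 CPM in cluster 2. Because both collagens were that high in all of these clusters, none was set apart as fibroblast-like, and the group was called collagen-rich. Cluster 0 was led by IL1RL1, PTGIR, TMEM119 and DLK1, and cluster 1 by the cell cycle genes UBE2C, RRM2 and TYMS. STMN2, SLC5A12 and SLPI led cluster 2, MGP and COL15A1 were among the leading genes of cluster 3, and C7, EDN1, HGF and RGS5 led cluster 4. Cluster 5 carried the smooth muscle markers ACTG2 (364 CPM), ACTA2 (1842 CPM) and TAGLN (2508 CPM) beside INHBA and CCL2. KRT14 and PI16 led cluster 16.

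The other named cells were cardiac, epicardial, endothelial and hepatic in character. Cardiomyocyte-like cells formed cluster 7, led by SHOX2 and PLN with TNNT2 at 4140.0 CPM, and cluster 8, led by MYL3, CKM, MYL2, NPPA and MYH7 with TNNT2 at 7867 CPM. Epicardial or mesothelial-like cells (cluster 9) held ITLN1 1296, UPK3B 327, TBX18 71.8 and WT1 69.4 CPM. Endothelial-like cells (cluster 10) held CLDN5 377, CDH5 239, KDR 505 and RAMP2 1326 CPM. Endoderm or hepatic-like cells (cluster 12) held APOA1 23198, SERPINA1 23044 and AFP 22283 CPM. Cluster 11, led by CPB1, KRT7, IL18, MFAP5 and NPY and richest in KRT18 (7903 CPM), stayed unnamed under the naming rule. It had 6 epicardial or mesothelial and 5 surface epithelial markers at least 2-fold up, with UPK3B at 280 CPM. The epicardial or mesothelial list did not lead among its top 10 genes. Cluster 13 mixed COL1A1 (4932 CPM) with TNNT2 (2359 CPM), and clusters 6, 14 and 15 were low in UMIs.

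No cluster was named from the remaining marker lists. Of the macrophage and blood genes, LAPTM5 peaked at 90.5 and AIF1 at 38.7 CPM in the endothelial-like cells and CD68 at 83.1 CPM in cluster 16 while PTPRC peaked at 0.160 CPM. The erythroid genes HBE1 (35.2 CPM in cluster 8) and HBG2 (25.9 CPM in cluster 10), and the surface epithelial genes KRT7 (627 CPM in cluster 11) and KRT14 (183 CPM in cluster 16), were local. STMN2 (1355 CPM in cluster 2) and NES (304 CPM in cluster 6) were the highest neural markers. ERBB3 (149 CPM in cluster 12) stood alone among the neural crest genes, with SOX10 at most 1.85 CPM. Pluripotency markers were low, with TDGF1 at 65.8 CPM in cluster 8, DPPA4 at 49.9 CPM in cluster 0 and POU5F1 at most 0.616 CPM. COL9A3 (170.3 CPM) and COL2A1 (128 CPM) led the chondrogenic list, and DES (383 CPM) and TNNT3 (40.6 CPM) the skeletal muscle list, where MYOD1 peaked at 1.23 CPM.

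Cardiomyocyte-like and hepatic-like cells took larger shares of the cryoinjured library at day 2 and smaller shares at day 4, and endothelial-like cells did the reverse. Cardiomyocyte-like cells were 10.3% [9.50 to 11.1] of cryoinjured and 5.85% [5.27 to 6.47] of non-cryoinjured cells at day 2, and 6.69% [5.92 to 7.54] and 9.38% [8.63 to 10.2] at day 4. Hepatic-like cells were 2.01% [1.66 to 2.40] and 0.333% [0.204 to 0.514] at day 2, and 0.263% [0.126 to 0.482] and 2.43% [2.05 to 2.87] at day 4. Endothelial-like cells were 1.92% [1.59 to 2.31] and 4.67% [4.15 to 5.23], then 4.23% [3.61 to 4.91] and 2.70% [2.29 to 3.15]. Collagen-rich cells were 78.7% [77.7 to 79.8] and 74.6% [73.4 to 75.7] at day 2, and 66.1% [64.6 to 67.6] and 73.9% [72.7 to 75.0] at day 4. Epicardial-like cells stayed close, at 3.19% and 3.67%, then 3.91% and 3.74%, and cluster 11 was 2.32% and 3.32%, then 4.23% and 3.17%. Mixed cells were 0.429% and 0.683%, then 1.47% and 0.670%.

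Depth and handling bear on these shares. Per the extract protocol the tissues were digested with collagenases and trypsin and sorted by flow cytometry into a suspension of mostly live cells, so the shares describe cells that passed both steps. Cells needed 1000 UMIs, and low-UMI clusters held 1.13% and 6.93% of cells at day 2 and 13.1% and 4.04% at day 4. Cluster 6, the largest of these, carried TTN at 16123 CPM and TNNT2 at 8643 CPM. When clusters 6 and 14 were counted as cardiomyocyte-like, the shares became 11.2% and 11.8% at day 2 and 18.6% and 13.2% at day 4, which reversed the direction of the cardiomyocyte-like difference on both days. The collagen-rich difference at day 2 also reversed under several settings, for example to -5.55 percentage points with at least 1000 detected genes. Within the collagen-rich cells, cluster 2 was 21.1% [20.04 to 22.2] and 6.42% [5.81 to 7.07] of all cells at day 2, and 8.64% [7.76 to 9.57] and 16.6% [15.6 to 17.6] at day 4.

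**Figure D1:**
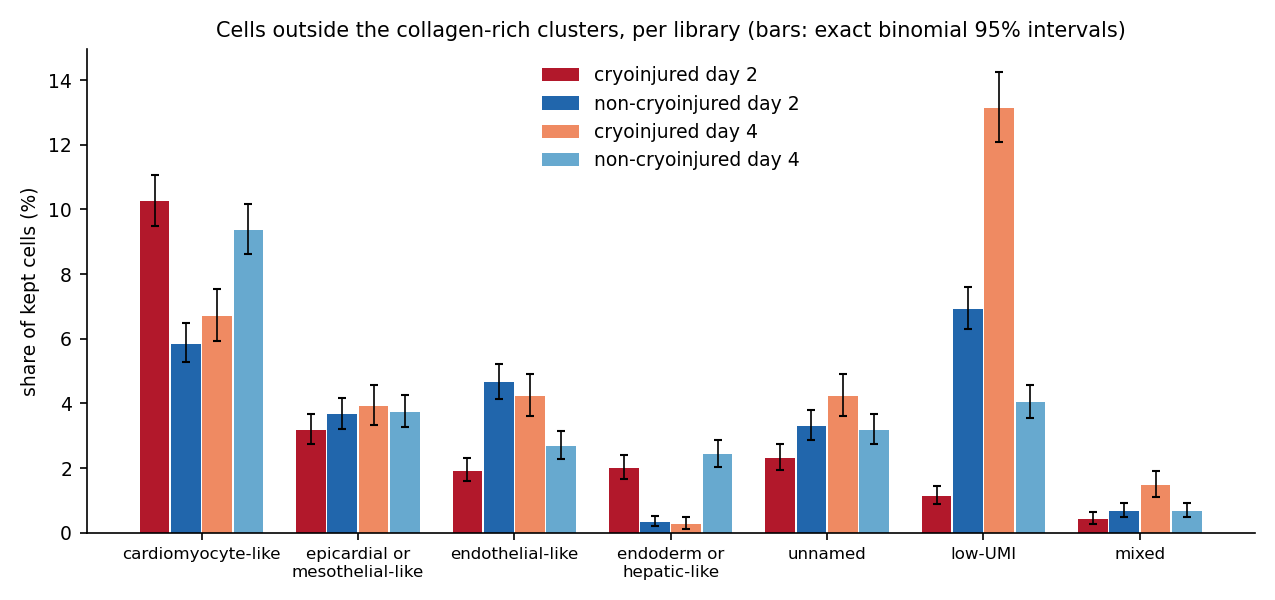
Share of kept cells in percent (vertical axis) in each class outside the collagen-rich clusters, 1 bar per library, with exact binomial 95% intervals. Cardiomyocyte-like cells were 10.3% of cryoinjured and 5.85% of non-cryoinjured cells at day 2, and 6.69% and 9.38% at day 4.

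At day 2, transcripts of hepatic secreted proteins and of CTGF, the matricellular growth factor CCN2, were higher in the cryoinjured library, while ASNS, PSAT1, DDIT4 and IL1RL1, the interleukin 33 receptor, were lower. The main fibrillar collagens were within 1.5-fold. Over all kept cells, COL1A1 was at 4264 CPM [4253 to 4275] and 4669 CPM [4657 to 4681], COL1A2 at 2113 and 2428 CPM and COL3A1 at 3875 and 3833 CPM. FN1 (715 and 678 CPM), POSTN (44.1 and 49.2 CPM) and ACTA2 (478 and 448 CPM) were also within 1.5-fold, whereas CTGF was at 359 CPM [355 to 362] and 181 CPM [178 to 183], a log2 ratio of 0.99. Within collagen-rich clusters POSTN was lower in cluster 4 (-2.49), cluster 1 (-1.09) and cluster 0 (-0.74) and higher in cluster 5 (1.06). ACTA2 was higher in cluster 0 (0.59), the largest of them. The natriuretic peptide gene NPPA was higher at 33.2 and 18.4 CPM (0.82), and NPPB (0.45), MYH6 (0.45), TNNT2 (0.41) and MYH7 (-0.06) were within 1.5-fold. In clusters 0 to 5, cluster 11 and endothelial-like cells MYH7 had ratios of -1.36 to -0.77, but its level was nearly alike in these clusters (19.04 to 23.5 CPM), and free RNA from cardiac cells was not told apart from expression. In cluster 11 NPPB stood at 2.79, and the cells behind its UMIs were not counted. Among genes with a mean of at least 50 CPM over the day 2 libraries, the 6 highest were hepatic or secretory. They were APOA1 at 859 CPM [854 to 864] and 140.4 CPM [138 to 143], SPINK1 (2.502), APOC3 (2.40), SERPINA1 (2.32), AFP (2.28) and FGB (2.27). RBP4 (2.39) lay under that minimum. Lowest was the epicardial lectin ITLN1 at 22.2 CPM [21.4 to 23.0] and 128 CPM [126 to 129.6] (-2.47). After it came IL1RL1 at 17.2 CPM [16.5 to 17.9] and 83.3 CPM [81.7 to 85.0] (-2.21), the asparagine synthetase gene ASNS at 27.5 CPM [26.7 to 28.4] and 97.51 CPM [95.7 to 99.3] (-1.79), and DDIT4, a brake on mTOR, at 67.8 and 182 CPM (-1.41). DHRS3 (-1.18) and CRHBP (-1.17) completed the 6 lowest genes above the minimum. The serine synthesis gene PSAT1 (-1.66), under the minimum, and the tryptophanyl-tRNA synthetase gene WARS (-1.05) were lower too.

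At day 4 many of these genes stood apart with the opposite sign. CTGF was lower in the cryoinjured library, at 157 CPM [154 to 159] and 371 CPM [367 to 374] (-1.24), while COL1A1 at 4377 CPM [4364 to 4389] and 3928 CPM [3917 to 3938], COL1A2 (0.02), COL3A1 (-0.10), FN1 (0.11), POSTN (-0.14) and ACTA2 (0.10) were within 1.5-fold. POSTN was higher in cluster 4 (1.20) and lower in cluster 2 (-0.59). Among genes with a mean of at least 50 CPM, IL1RL1 was the highest over all kept cells at 125 CPM [122 to 127] and 17.8 CPM [17.1 to 18.5] (2.74). It was followed by ASNS at 118 CPM [116 to 119.9] and 36.5 CPM [35.5 to 37.5] (1.66), ITLN1 (1.65), PSAT1 (1.42), the methyltransferase gene NNMT (1.30) and WARS (1.14). DDIT4 (1.08) and CRHBP (0.70) were higher as well, and DHRS3 (0.32) was not. The lowest genes above that minimum were again hepatic, with TTR at 15.3 CPM [14.5 to 16.1] and 181 CPM [179 to 183] (-3.48), AFP (-2.72), APOA1 (-2.11), FGB (-2.06), RBP4 (-2.02) and AMBP (-1.90). SPINK1 (-3.05), SERPINA1 (-1.80) and APOC3 (-1.495) belonged to the same group. NPPA (26.4 and 47.9 CPM, -0.84) and NPPB (13.5 and 26.8 CPM, -0.94) were lower, and TNNT2 (-0.08), MYH6 (-0.08) and MYH7 (0.42) were within 1.5-fold. In clusters 0 to 5, cluster 11 and endothelial-like cells MYH7 had ratios of 0.87 to 1.89, again with free RNA not told apart. MYH6 in clusters 0 to 3 (0.84 to 1.28), cluster 11 (0.96) and epicardial-like cells (0.77) is open to the same reading. NPPB stood at -3.09 in cluster 1, -2.99 in cluster 5 and 3.79 in endothelial-like cells, and the cells behind its UMIs were not counted.

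Opposite signs on the 2 days were common among the genes compared. Of 2681 genes with a mean of at least 50 CPM 74.3% had opposite signs. The day 2 and day 4 injury ratios had a Pearson correlation of -0.81 and a Spearman correlation of -0.66. Of 41 genes that differed by 1.5-fold on both days all 41 had opposite signs. Within cell groups 2 of 20 such genes in cluster 11 and 1 of 24 in epicardial-like cells had the same sign. Cryoinjured day 2 was nearest to non-cryoinjured day 4, with 3 genes apart by 1.5-fold, and cryoinjured day 4 to non-cryoinjured day 2, with 9. The pairs that shared a day differed in 84 genes at day 2 and 55 at day 4. Those that shared an arm differed in 61 (cryoinjured) and 70 (non-cryoinjured). Within cell types the correlation ran from -0.80 in cluster 2 and -0.78 in cluster 0 to -0.48 in cardiomyocyte-like (-0.29 with cells thinned to 3000 UMIs), -0.55 in endothelial-like and -0.36 in cluster 11 cells.

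**Figure D2:**
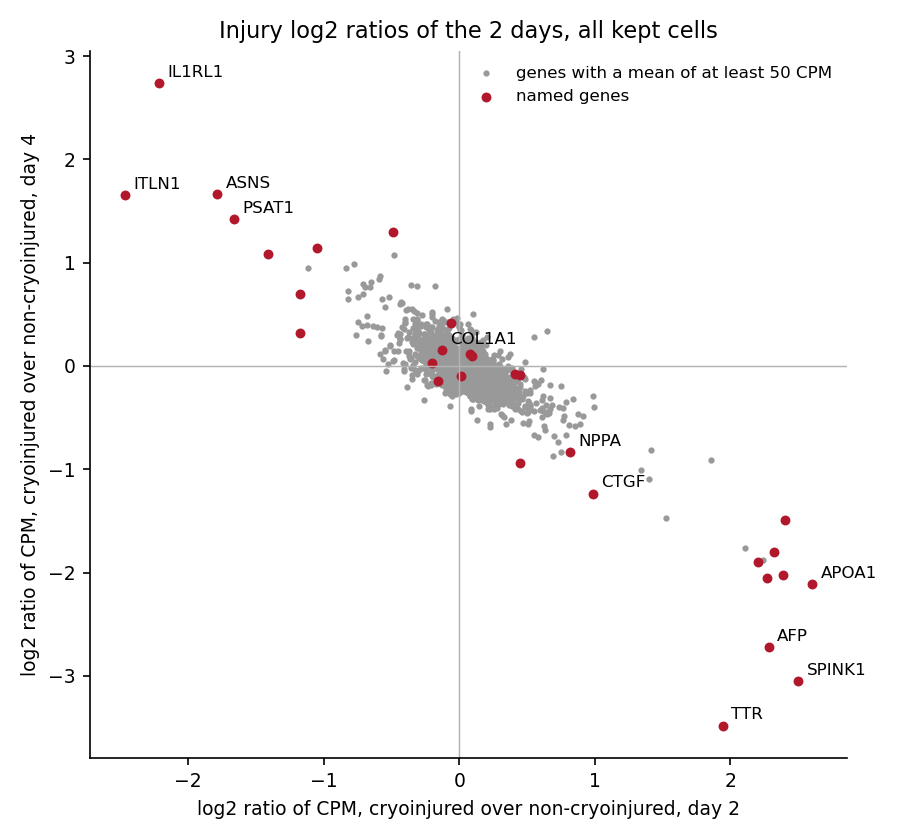
Each point is a gene with a mean of at least 50 CPM over all kept cells, placed by its log2 ratio of cryoinjured over non-cryoinjured CPM at day 2 (horizontal axis) and day 4 (vertical axis). CTGF lay at 0.99 and -1.24, IL1RL1 at -2.21 and 2.74, and COL1A1 near the center.

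In cluster 0 and in the dividing cluster 1, CTGF and CYR61 were higher in the cryoinjured library at day 2 and lower at day 4, and ASNS, PSAT1 and DDIT4 did the opposite. CTGF in cluster 0 was at 351 CPM [344 to 359] and 138 CPM [134 to 143] at day 2 and 136 CPM [131 to 141] and 363 CPM [356 to 370.3] at day 4 (1.34 and -1.41). CYR61 (0.89 and -0.61), another matricellular YAP target, ran beside it, and NR4A1 (0.86), the protease gene HTRA1 (0.84), PROK1 (1.09) and MYLIP (0.83) were higher at day 2. ASNS (-2.09 and 2.43), PSAT1 (-1.997 and 2.41), WARS (-1.26 and 1.46), DDIT4 (-1.40 and 1.11), the pentraxin gene PTX3 (-1.13 and 1.33) and NNMT (-1.06 and 2.20) were lower, then higher. IL1RL1 (-1.86 and 2.93) did the same but helps define cluster 0. DHRS3 (-1.39) was lower at day 2, MGP (1.37) higher at day 4, and KLK6 (-0.80), COL4A6 (-0.79), PDIA4 (-0.73), TNNT1 (-0.69) and ITGA8 (-0.68) lower at day 4. COL1A1 in cluster 0 was at 6079 and 5916 CPM and then 5663 and 5899 CPM. ACTA2 there was higher at day 2, at 249 and 165 CPM (0.59), and within 1.5-fold at day 4 (-0.33). In the dividing cluster 1, CTGF (1.25 and -1.42), CYR61 (0.88 and -0.72), IL1RL1 (-2.41 and 1.87), DDIT4 (-1.91 and 1.48), ASNS (-1.83 and 1.60) and PSAT1 (-1.55 and 1.28) followed suit. CTSV (1.000), KRT19 (0.98), NR4A1 (0.95) and HAPLN1 (0.83) were higher and FHL2 (-1.02) and DHRS3 (-1.74) lower there at day 2. At day 4 NNMT (1.31) was higher, and SLC2A1 (-0.97), TAGLN (-0.89), SLC9A3R1 (-0.76) and EBPL (-0.67) were lower, while S100A8 (6.91) came almost wholly from 1 cell.

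The other collagen-rich states carried their own genes on the same alternating pattern. Cluster 3, the state with the most COL1A1, had CTGF at 247 CPM [238 to 256] and 77.3 CPM [72.4 to 82.4] at day 2 (1.66, then -1.14) with CYR61 (1.499), CD44 (1.22), KRT19 (1.25) and the metallothioneins MT1E (1.32 and -1.28) and MT2A (1.19 and -0.82). There IL1RL1 (-1.43 and 3.12), FHL2 (-1.28 and 0.98), IGFBP5 (-1.93 and 1.87), BGN (-1.09) and LXN (-1.09) ran the other way, with FAM107B (1.31) and MTUS1 (1.19) higher and S100A10 (-0.78) and PRCD (-1.05) lower at day 4. Cluster 2 had NPY (2.73 and -1.35), CTSV (2.11 and -1.71), SLC7A7 (1.85 and -1.55), PROK1 (1.70 and -1.34) and KRT7 (2.25 and -1.95) higher, then lower. LGALS1 (-1.18 and 1.12), CXCL14 (-1.49 and 1.09), HSPB6 (-0.98 and 1.25) and DLK1 (-1.14 and 0.70) were lower, then higher, and SLPI (2.47) and SLC5A12 (1.80), higher at day 2, define that cluster. Cluster 4 had HAPLN1 (1.47 and -1.58) and CCDC80 (1.14), BEX1 (0.998) and CTGF (1.22) higher at day 2. NR2F1 (-1.52 and 1.08), DIO3 (-1.19 and 0.97), PTN (-1.31 and 0.73) and ECM1 (-1.56 and 0.88) were lower, then higher, as was its defining gene HGF (-1.88 and 1.47). KLF2 (0.94), HTRA3 (0.83) and IFITM1 (0.82) were higher and TNNI1 (-0.75) and DOK4 (-0.74) lower in cluster 4 at day 4.

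Cluster 5, the contractile state, had PSAT1, ASNS and PTX3 lower at day 2 but not apart at day 4. At day 2 KRT19 (1.13), HMGA1 (1.01), AQP1 (0.86) and EZR (0.84) were higher. IL1RL1 (-3.06), PSAT1 (-2.38), ASNS (-2.09), DDIT4 (-1.96), DHRS3 (-1.77) and PTX3 (-1.59) were lower, and at day 4 PSAT1 (0.02), ASNS (0.10) and PTX3 (0.11) were within 1.5-fold. At day 4 MGP, an inhibitor of calcification (414 and 135 CPM, 1.61), and TIMP1, an inhibitor of metalloproteinases (3084 and 1263 CPM, 1.29), were higher with LXN (1.66), IGFBP6 (1.38), IFITM1 (1.17) and HLA-B (1.12). The YAP targets ANKRD1 (25.6 and 125 CPM, -2.25) and CTGF (217 and 645 CPM, -1.57) were lower, as were EZR (-1.22), SBSPON (-1.07), ANXA3 (-0.96) and SLC2A1 (-0.92). The cluster 5 inflammation list had a median of -0.56 at day 2, with 9 of 19 members lower, and its cell cycle list a median of 0.41, with 8 of 22 higher.

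Cardiomyocyte-like cells held the main contractile genes at similar levels on both days, and MYL2, the ventricular light chain gene, and CTGF differed on both days. TNNT2 was at 5509 CPM [5461 to 5558] and 5863 CPM [5789 to 5938] at day 2 and 6162 CPM [6088 to 6237] and 6674 CPM [6618 to 6729.7] at day 4, and MYH6 ratios were -0.04 and -0.01. MYH7 (-0.35 and 0.40) was within 1.5-fold. MYL2 was lower at day 2, 102 CPM [95.3 to 109] and 405 CPM [386 to 425], and higher at day 4, 525 CPM [504 to 547] and 112 CPM [104 to 119]. Cluster 8, which MYL2, NPPA and MYH7 lead, held 255 of 598 and 141 of 351 cells of the class at day 2, and 134 of 255 and 267 of 532 at day 4. CTGF (0.98 and -0.92) followed the collagen-rich cells, NPPA was at 448 and 327 CPM and then 390.1 and 673 CPM (-0.78), and NPPB was within 1.5-fold on both days (0.01 and -0.54). RCAN1 (0.98), a calcineurin target, DUSP1 (0.97), GSTM4 (0.70), UCHL1 (0.69) and COL2A1 (0.69) were higher at day 2. BGN (-1.05 and 1.05), TCAP (-0.81 and 1.18), PEG10 (-0.99), MIR143HG (-0.96) and MIR145 (-0.88) were lower at day 2. DES (0.95), PTN (0.94), TYMS (0.96) and SAMD1 (0.97) were higher, and S100A10 (-0.68), FRMD3 (-0.65) and TUBA1C (-0.62) lower, at day 4, but with clusters made within each library BGN reversed to -0.69 and PTN to -0.058 at day 4. The matrix genes COL1A1 (0.02 and 0.35), COL1A2 (-0.14 and 0.32), COL3A1 (-0.18 and 0.14) and FN1 (0.22 and 0.40) were within 1.5-fold, and POSTN (10.3 and 49.3 CPM, then 32.5 and 6.44 CPM) was lower, then higher. For POSTN free RNA from collagen-rich cells was not told apart from expression. HBE1 (-6.54) was lower at day 2 only because a pair of non-cryoinjured cells held nearly all its UMIs. In the cardiomyocyte-like class the sarcomere list had medians of -0.09 and -0.02, cell cycle 0.28 at day 4 with 8 of 33 members higher, and lipid and cholesterol -0.34 at day 2 with 7 of 20 lower.

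In epicardial-like cells TCF21, ACTA2, COL1A1 and FN1 were higher at day 2 and mitotic genes lower at day 4. In the epicardial or mesothelial-like class TCF21, a gene of epicardium-derived fibroblasts, was at 97.8 CPM [90.9 to 105] and 32.7 CPM [28.6 to 37.2] at day 2 and 44.2 and 83.8 CPM at day 4. HAPLN1 (2.25), S100A6 (1.87), LGALS1 (1.57), KRT7 (1.82) and ACTA2 (419 CPM [405 to 434] and 144 CPM [135 to 153], 1.54) were higher at day 2, as were COL1A1 (1547 and 866 CPM, 0.84), FN1 (1.13) and NPPB (0.92). COL1A2 (0.51), COL3A1 (0.11), POSTN (0.38) and CTGF (-0.11) were within 1.5-fold, and the collagen list median was 0.12. MGP (-2.06 and 1.85), INADL (-1.45), SLC34A2 (-1.36) and HHIP (-1.19) were lower at day 2, with the defining genes ITLN1 (-2.62 and 1.60) and UPK3B (-1.17). At day 4 CXCL14 (1.16), the cell cycle inhibitor gene CDKN1C (0.83), PCP4 (0.81) and DES (0.74) were higher. CTGF (-1.02), NPPB (-1.20), SLC2A1 (-1.01) and the mitotic genes PLK1 (-1.04) and CDKN3 (-1.04) were lower, and most UMIs of KRT7 (-1.36) on the higher side came from 1 cell. The cell cycle list had a median of -0.83 at day 4, with 27 of 33 members lower, and at day 2 the medians were 0.55 for inflammation, 0.39 for interferon and 0.32 for myofibroblast genes.

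EDN1 differed in endothelial-like cells on both days and ACTA2 and TAGLN in cluster 11 at day 2, and in both the cell cycle list had a negative median at day 4. In endothelial-like cells EDN1, the endothelin 1 gene, was at 230.5 CPM [216 to 246] and 109 CPM [102 to 117] at day 2 and 112 and 228 CPM at day 4, and HAPLN1 (0.89 and -0.86) ran with it. S100A6 (1.05), UCHL1 (0.85) and SLC2A3 (0.79) were higher at day 2. NTS (-2.30 and 1.98), ACP5 (-1.25 and 1.04), ECM1 (75.5 and 152 CPM, then 123 and 56.6 CPM), FCN3 (-0.87 and 1.08) and HSPA1A (-0.85 and 0.87) were lower, then higher. CLEC4M (-1.53), RAMP1 (-0.89) and DNASE1L3 (-0.89) were lower at day 2 and RNASE1 (1.08) higher at day 4. The mitotic genes PLK1 (-0.76), AURKA (-0.76), CKS2 (-0.72) and UBE2C (-0.71) were lower at day 4, where 8 of 34 cell cycle genes were lower (median -0.43), and PF4 (1.37 and -4.14) came from a few cells. In cluster 11 ACTA2 (2.04), TAGLN (1.39), GADD45A (1.35), RCAN1 (1.24) and LOX (1.13) were higher and PLA2G2A (-1.09), BCAM (-1.04), CRABP2 (148 and 297 CPM) and EDN3 (-0.94) lower at day 2, with 5 of 19 myofibroblast contractile genes higher (median 0.22). UBE2C (-2.02), TOP2A (-1.77), MKI67 (-1.68), CDKN3 (-1.96), PLK1 (-1.96) and CDC20 (-1.66) were lower and CCND2 (0.86) and TXNIP (0.75) higher at day 4, where 23 of 33 cell cycle genes were lower (median -1.19).

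Gene lists tied to fibrosis differed little over all kept cells. The collagen list had a median log2 ratio of -0.13 at day 2, with 0 of 15 members higher and 2 lower (COL15A1 -0.82, COL14A1 -0.64), and 0.02 at day 4, with COL15A1 (0.72) higher. Non-collagen matrix had medians of -0.03 on both days, with MFAP5 (1.07) higher and BGN (-0.76) lower at day 2 and MGP (253 and 119.7 CPM) higher at day 4. Matrix remodelling was -0.05 at day 2 and 0.13 at day 4, where 3 of 25 members were higher, TIMP1 (1646 and 959 CPM) among them. The TGF-beta response list was at -0.03 and 0.08 and, like matrix remodelling (8 of 10), above 0 in most cell groups at day 2 (9 of 10), with CTGF on opposite sides, INHBA (-0.64) lower at day 2 and ID2 (-0.69) lower at day 4. The median gene of at least 50 CPM was itself above 0 in every cell group at day 2 (0.04 to 0.10). At day 4 it was below 0 in every group (-0.09 to -0.02), so signs of list medians are to be read beside that shift. All 20 myofibroblast contractile genes were within 1.5-fold on both days (medians 0.00 and 0.10), TAGLN (0.36) and CALD1 (0.34) included. YAP and SRF targets had medians of 0.11 and -0.15, with CTGF, CYR61 (0.86 and -0.58) and EGR1 (0.78 and -0.48) higher at day 2 and FHL2 (-0.74) lower. Within cell groups the YAP and SRF median was above 0 in 9 of 10 at day 2 (-0.04 to 0.36). At day 4 it was below 0 in all 10 (-0.34 to -0.08).

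Sarcomere, calcium handling and fetal gene lists had positive medians over all kept cells at day 2 and negative ones at day 4, which most cell groups did not share on both days. Sarcomere genes had a median of 0.28 at day 2, at percentile 100 among random lists matched on level, with 5 of 24 members higher and MYL2 (-1.10) and TTN (-0.84) lower. At day 4 the median was -0.07, with MYL2 (1.83) and TTN (0.94) higher, and above 0 in 7 of 10 cell groups (-0.23 to 0.69). Calcium handling was at 0.25 and -0.14, with SLN (1.91 and -1.20) and PLN (0.67). Fetal and stretch-stress genes were at 0.19 and -0.17, with NPPA higher, then lower with NPPB, and cardiac transcription factors at 0.08 and 0.02, with MEF2C (-0.82) lower at day 2, TBX2 (0.59) higher at day 4 and NKX2-5 (0.43) and HAND1 (0.39 and -0.33) within 1.5-fold.

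Stress, cycle and metabolic lists differed by small amounts over all kept cells. Immediate early genes had the largest median at day 2, 0.39 with 7 of 19 higher (percentile 100), EGR1 (353 and 206 CPM) and EGR2 (0.70) leading and FOS (0.40) within 1.5-fold, and -0.06 at day 4, with KLF4 at 0.54. Many of these genes also respond to tissue dissociation. Cell cycle genes were at -0.30 at day 2 (percentile 0; CENPF -0.53, UBE2C -0.38) and -0.04 at day 4 (percentile 37.0), with 0 of 33 members reaching 1.5-fold. Within cell groups the cell cycle median was above 0 in 9 of 10 at day 2 (-0.12 to 0.41) and in 1 of 10 at day 4 (-1.19 to 0.28), so the value over all kept cells at day 2 had the opposite sign to most groups. At day 4 the value over all kept cells was 0.15 with cells thinned to 3000 UMIs, and the dividing cluster 1 held 11.2% and 17.1% of cells at day 2 and 13.9% and 12.5% at day 4. Hypoxia and glycolysis was at 0.07 and -0.10, with SLC2A1 (0.75 and -0.83) and DDIT4 on opposite sides. Oxidative phosphorylation was at 0.16 and -0.13, its sign shared by all 10 compared cell groups on each day, with PDK4 (0.80) and FABP3 (0.66) higher at day 2. The p53 list was at -0.03 and 0.20, with SESN2 (-0.67 and 0.78), GADD45A (0.61) and CDKN1A (0.65). Its day 4 median was above 0 in all 10 cell groups (0.02 to 0.28). Heat shock genes were at -0.02 and -0.10, but within the 10 cell groups all medians were above 0 at day 2 (0.04 to 0.27) and below 0 at day 4. The median gene of at least 50 CPM had the same signs in all 10 groups (0.04 to 0.10, then -0.09 to -0.02). The signs of heat shock, oxidative phosphorylation and cell cycle medians within groups therefore do not by themselves set these lists apart. No heat shock gene reached 1.5-fold over all kept cells, HSPA8 (0.30 and -0.36) and DNAJB1 (0.32) included. The unfolded protein response list was at 0.10 with 4 of 21 members lower, then -0.01 with 4 higher, while its amino acid members CHAC1 (-1.86 and 1.53) and ASNS stood far out and CALR (0.37 and -0.38) did not. Lipid and cholesterol genes were at -0.06 and -0.11, with ABCA1 (0.66) higher at day 2, and the metallothionein, iron and oxidative stress list at 0.13 with 4 of 19 members higher, then -0.13, with MT1E (0.79) and MT1F (0.86 and -1.06) higher, then MT1F lower and SLC7A11 (1.48) higher.

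Interferon, inflammation and growth factor lists had positive medians at day 4 over all kept cells. The interferon list was at -0.08 at day 2 and 0.19 at day 4 (percentile 100, 3 of 22 members higher), with HLA-B (63.6 and 33.9 CPM) and IFITM1 (118 and 68.4 CPM) higher and positive medians from 0.09 to 0.27 in all 10 compared cell groups. Inflammation and chemokine genes were at -0.12 with 4 of 18 lower, then 0.07 with 3 higher, with C3 (1.31) higher and IL6ST (-0.71 and 0.70) and IL1RL1 lower, then higher. Wnt and BMP genes were at 0.07 and -0.13, led by FST (1.501 and -0.91) and WNT2 (-0.59 and 1.01). Growth factors and angiogenesis were at -0.14 with 5 of 29 lower, then 0.13 with 4 of 30 higher, with HGF (-1.56 and 1.08), EDNRA (-0.92) and KITLG (0.93). Epicardial activation and EMT genes were at 0.15 and -0.03, with ALDH1A1 (1.99 and -1.77) and KRT19 (0.99) while VIM (0.16 and -0.05) was even.

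**Figure D3:**
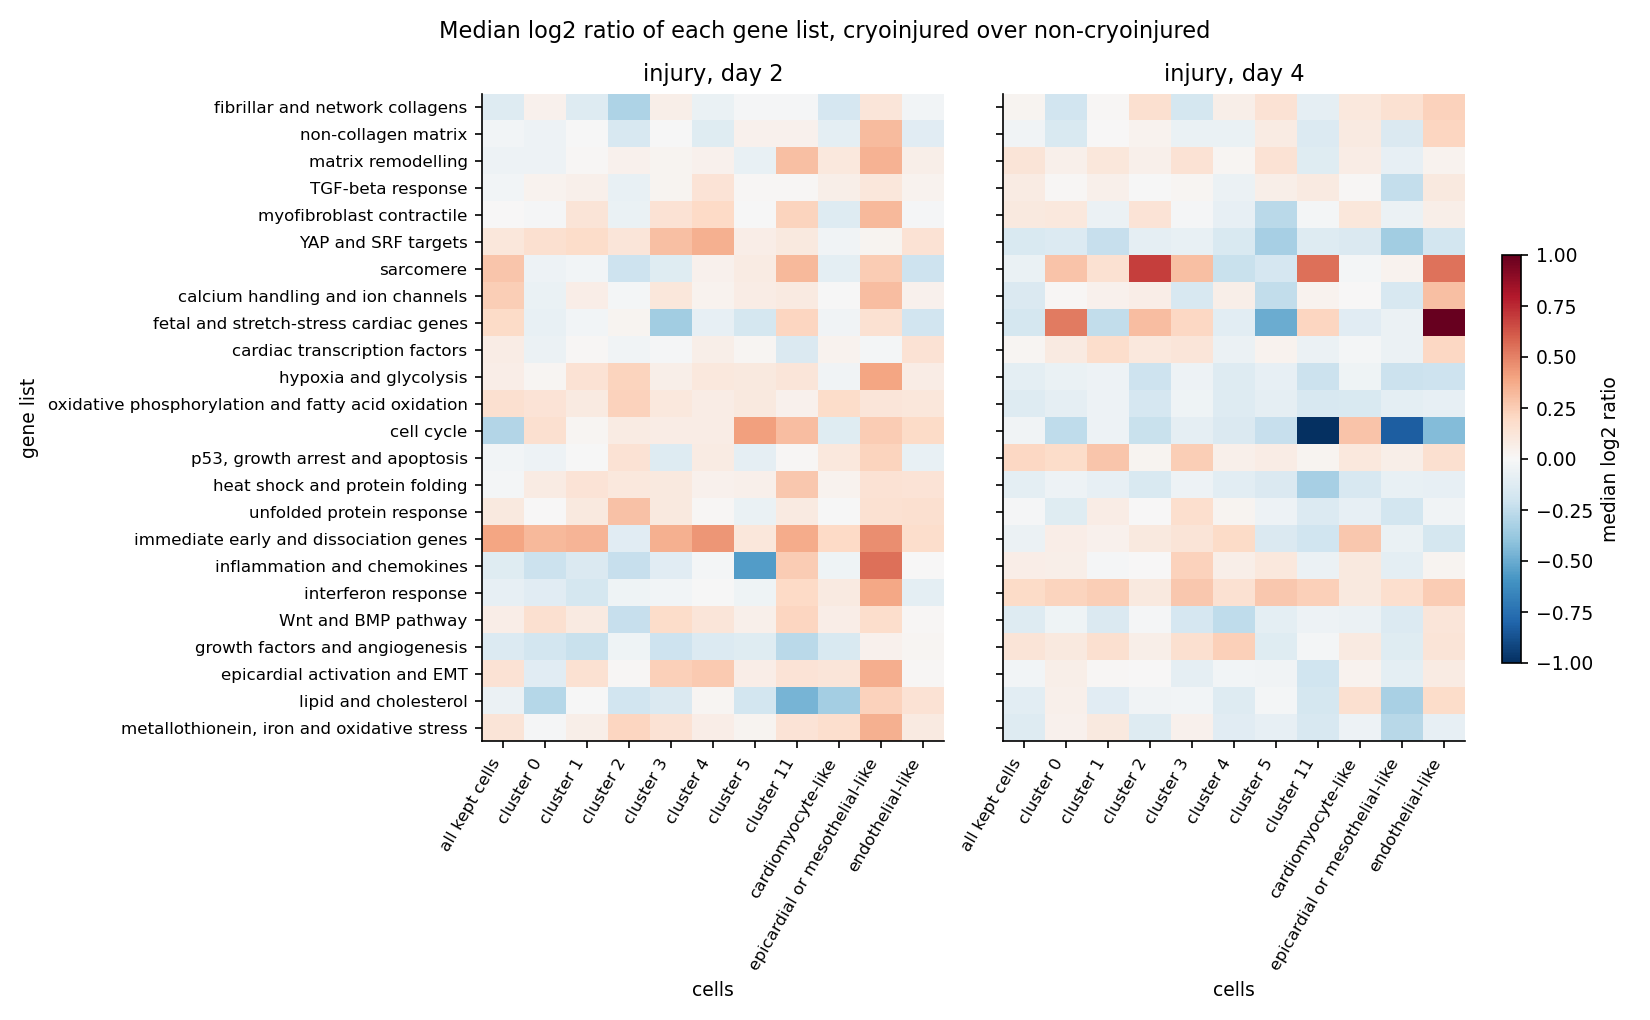
Color shows the median log2 ratio of cryoinjured over non-cryoinjured CPM for each gene list (vertical axis) in all kept cells and in each compared cell group (horizontal axis), at day 2 on the left and day 4 on the right. The interferon medians at day 4 lay between 0.09 and 0.27 in all 10 groups, and the cluster 11 cell cycle median was -1.19.

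From day 2 to day 4 the named genes mostly had opposite signs in the arms. CTGF at day 4 was -1.19 log2 from its day 2 value in cryoinjured and 1.03 in non-cryoinjured tissue, and AFP (-2.41 and 2.59) and TTR (-2.26 and 3.17) had the same signs. IL1RL1 (2.79 and -2.17), ASNS (2.06 and -1.39), DDIT4 (1.52 and -0.97), PSAT1 (1.85 and -1.23), ITLN1 (2.86 and -1.26) and NNMT (0.89 and -0.90) had the reverse. COL1A1 (0.04 and -0.25) and COL3A1 (-0.16 and -0.04) were within 1.5-fold, ratios of ACTA2 (-0.33 and -0.33) and FN1 (-0.21 and -0.25) were negative within 1.5-fold in both arms, and NPPA (-0.32 and 1.33) higher only without injury. In cardiomyocyte-like cells TNNT2 (0.16 and 0.19) and MYH6 (0.28 and 0.25) were within 1.5-fold while MYL2 (2.36 and -1.85) and CTGF (-1.16 and 0.74) diverged. Over all kept cells the time medians in cryoinjured and non-cryoinjured tissue were -0.34 and 0.14 for immediate early genes, 0.27 and -0.06 for the cell cycle (above 0 in 3 and 9 of 10 cell groups), 0.11 and 0.51 for the sarcomere, -0.15 and 0.24 for YAP and SRF targets and 0.01 and -0.19 for collagens. The correlation of the time ratios between the arms was -0.84 over all kept cells, but -0.31 in cardiomyocyte-like and -0.43 in endothelial-like cells.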

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

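All tests weighed here were chosen only after the results had been seen, and none of the differences between days below was tested, since each condition was 1 library.

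What drew attention was a difference between the days: the injury ratio had opposite signs at day 2 and day 4. Across genes the Pearson correlation of both ratios was -0.81 over all kept cells, and the Spearman correlation was -0.66. Of 199 gene and cell group pairs named within clusters or classes 96 were 1.5-fold apart on both days, 95 in opposite directions and 1 in the same.

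The opposite signs were weighed first. With every cell thinned to the same number of UMIs the correlation was -0.777 over all kept cells. Thinning evens the weight of deep and shallow cells in the sums, so this argues only against that weight as the source. It cannot remove an effect of depth on each cell's profile, so depth is not excluded. In cardiomyocyte-like cells the correlation was -0.48 and with thinning -0.29. Fewer UMIs after thinning also mean more counting noise, so the weaker value does not decide about depth there. With equal weights for the clusters the correlation over all kept cells was -0.657, which argues against different shares of clusters. The injury by day contrast held 83.9% of the squared differences between the libraries, and the unlike pairs of day and arm differed 0.416 times as much as the matched pairs. Exchanged library names predict these values, and so do tissue batches that pair cryoinjured day 2 with non-cryoinjured day 4. Names and batches cannot be told apart, because no library is replicated. An injury response that turns between the days predicts opposite signs, but alone it leaves the non-cryoinjured libraries alike. These differed by 1.5-fold in 70 genes, and the cryoinjured libraries in 61, beside 3 and 9 for the unlike pairs. Such a response would also need a change between the days without injury, and with that it cannot be told apart either. Some measures of cell quality also paired cryoinjured day 2 with non-cryoinjured day 4. Barcodes over 25% mitochondrial UMIs were 21.7% and 20.4% in these, against 32.6% in cryoinjured day 4 and 28.9% in non-cryoinjured day 2. Low-UMI cells were 1.13% and 4.04% against 13.1% and 6.93%. Median UMIs of kept cells paired only in part, at 21197 and 21733 against 24933 and 17466. A difference in handling that pairs the libraries was not tested. An injury response is the biological explanation that the design names, and it stays untested.

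Hepatic transcripts over all kept cells were weighed next. The ratios at day 2 and day 4 were 2.61 and -2.11 for APOA1, 2.502 and -3.05 for SPINK1, 2.40 and -1.50 for APOC3, 2.32 and -1.80 for SERPINA1, 2.28 and -2.72 for AFP, 2.27 and -2.06 for FGB, 1.95 and -3.48 for TTR, 2.39 and -2.02 for RBP4 and 2.21 and -1.90 for AMBP. Hepatic-like cells held 92.7% of the hepatic marker UMIs of cryoinjured day 2 and 93.1% of those of non-cryoinjured day 4. They held 87.3% in cryoinjured day 4 and 87.4% in non-cryoinjured day 2, with only 10 and 20 such cells. The class was named by these markers, so the percentages do not bear on the number of its cells. Its share differed by 1.68 percentage points at day 2 and -2.17 at day 4, so a different number of such cells could account for the ratios. Free RNA stays open for the remainder. Outside hepatic-like cells, hepatic marker levels differed between cell groups 2.18-fold in cryoinjured day 2 and 2.15-fold in non-cryoinjured day 4. The difference was 4.17-fold in cryoinjured day 4 and 4.67-fold in non-cryoinjured day 2. The lowest level in any of these groups was 207 CPM in cryoinjured day 2 and 218 CPM in non-cryoinjured day 4, with 117 and 138 hepatic-like cells. It was 62.6 CPM in cryoinjured day 4 and 49.7 CPM in non-cryoinjured day 2. Levels that rise with the number of hepatic-like cells go with free RNA. The same libraries pair in many other genes, so this does not settle it. Cardiomyocyte-like cells were highest in each library, and their cluster 8 held the list members CLDN6 at 209 and EPCAM at 76.8 CPM. The summed level is thus not a measure of hepatic RNA alone. With libraries pooled, AFP ran from 27.6 to 52.6 CPM over the clusters of the compared groups. SERPINA1 ran from 19.3 to 42.0 CPM, but APOA1 from 25.1 to 92.0 CPM. Whether injury or the make-up of each batch of tissues set the number of hepatic-like cells was not tested.

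The genes ASNS, PSAT1, WARS and DDIT4 formed the third pattern: ASNS had ratios of -1.79 and 1.66, PSAT1 of -1.66 and 1.42, WARS of -1.05 and 1.14 and DDIT4 of -1.41 and 1.08. A shared shift could lie behind them, because the cytosolic aminoacyl-tRNA synthetases that were not named by rank had a median of -0.31 at day 2 and 0.32 at day 4, outside the central 95% of random lists on both days. Whether injury, culture medium or tissue batch set that shift cannot be said from 1 library per condition.

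Other results with opposite signs on the days are given as values. The shares of collagen-rich cells differed by 4.18 percentage points at day 2 and -7.80 at day 4, but 5 alternatives turned the day 2 difference, as far as -5.55. Those of cardiomyocyte-like cells differed by 4.42 and -2.68 points, reversed to -0.588 and 5.33 with low-UMI cardiomyocyte clusters included, and those of endothelial-like cells by -2.74 and 1.53 points. CTGF had ratios of 0.99 and -1.24 and NPPA of 0.82 and -0.84. ITLN1 stood at -2.47 and 1.65, IL1RL1 at -2.21 and 2.74 and CRHBP at -1.17 and 0.70. These are values over all kept cells, so numbers of cells can enter. CRHBP was a leading gene of endothelial-like cells, which were 1.92% and 4.67% at day 2 and 4.23% and 2.70% at day 4. Inside cardiomyocyte-like cells (10.3% and 5.85% at day 2) NPPA was within 1.5-fold at day 2 (448 and 327 CPM) and lower at day 4 (-0.78). Numbers of cells could account for CRHBP and in part for NPPA at day 2, which was not tested.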

How the results depend on the processing

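The values followed here were chosen after the main results were known, and the top 6% of doublet scores and the low-UMI cardiomyocyte clusters were alternatives chosen after seeing the data. Endothelial-like and hepatic-like share differences kept their direction under every alternative run, and the correlation of the injury ratios over all kept cells stayed between -0.83 and -0.78. Genes were followed only over all kept cells and in cardiomyocyte-like cells, so genes of the other cell groups went through no alternative. Of the gene values 292 stayed within the spread of the main value, 318 left it and 2 reversed. For shares the counts were 64, 21 (1 with the sign turned) and 7. For list medians 157 stayed and 3 left, all 3 with the sign turned, and for correlations 9 stayed and 4 left. No paired analysis was possible because the 4 samples of each condition were pooled in 1 library. The alternatives for edgeR (DESeq2, no filter on low counts, a replicate block and leaving out replicates) were not run, since cells could not be assigned to samples. Thinning left out 66, 370, 302 and 197 shallow cells (cryoinjured and non-cryoinjured day 2, then day 4), and depth limits what low-UMI cells can show. For every value below the cause was not tested.

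Share differences are in percentage points, with main values of 4.18 (day 2) and -7.80 (day 4) for collagen-rich, 4.42 and -2.68 for cardiomyocyte-like, -2.74 for endothelial-like at day 2, -0.473 for epicardial-like at day 2 and 1.68 and -2.17 for hepatic-like cells. With at most 10% mitochondrial UMIs, day 2 differences were 5.71 for collagen-rich, 2.48 for cardiomyocyte-like and -3.42 for endothelial-like cells. With no limit on mitochondrial UMIs, collagen-rich cells differed by 7.23 at day 2 and -15.1 at day 4, and cardiomyocyte-like cells by 2.94 at day 2. With at least 1000 detected genes, collagen-rich cells reversed to -5.55 at day 2 and stood at -1.60 at day 4, and hepatic-like cells at -1.27 at day 4. At resolution 0.3 the cardiomyocyte-like difference at day 2 was 3.17. At resolution 1.0 the collagen-rich difference reversed to -2.96 at day 2 and was -3.18 at day 4, and the hepatic-like differences were 1.28 and -1.23. With clusters made within each library, collagen-rich cells reversed to -0.557 at day 2 and stood at -4.99 at day 4, cardiomyocyte-like cells at 3.02 and -4.57, and epicardial-like cells reversed to 1.05 at day 2. With 4000 variable genes, collagen-rich cells reversed to -2.61 at day 2 and stood at -2.66 at day 4. With the top 6% of doublet scores removed, collagen-rich cells reversed to -1.23 at day 2 and stood at -3.22 at day 4, cardiomyocyte-like cells at 3.23 at day 2, and hepatic-like cells at 1.21 and -1.10. With low-UMI clusters led by the cardiomyocyte list included, the cardiomyocyte-like differences reversed to -0.588 and 5.33.

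In the cardiomyocyte-like class taken from clusters made within each library, BGN reversed to -0.69 and PTN to -0.058 at day 4. Over all kept cells at day 4, the collagen list median was -0.0089 with cells thinned to 3000 UMIs, and the cell cycle median 0.15 with thinning and 0.10 with the mean of each cell's CPM. The correlation of the injury ratios was -0.63 in cluster 0 with thinning, and in cardiomyocyte-like cells -0.29 with thinning, -0.38 with at most 10% mitochondrial UMIs and -0.38 with clusters made within each library.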

Other observations

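The test of the synthetases given here was chosen only after the named genes had been seen.

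Cytosolic synthetase genes differed most in collagen-rich clusters 0 to 3 and, at day 2 only, in cluster 5. Over all kept cells the 20 cytosolic aminoacyl-tRNA synthetases had a median log2 ratio of -0.34 at day 2, with 5 lower, and 0.35 at day 4, with 6 higher, and the 16 mitochondrial ones 0.08 and -0.06 with none at 1.5-fold. In cluster 0 the cytosolic medians were -0.48 and 0.63, in cluster 1 -0.40 and 0.37, in cluster 2 -0.28 and 0.31 and in cluster 3 -0.39 and 0.58. Cluster 5 had -0.53 at day 2 and 0.05 at day 4, and cluster 4 -0.10 and 0.07. Cardiomyocyte-like cells (-0.0054 and -0.0033), endothelial-like cells (0.06 and 0.08) and cluster 11 (0.03 and -0.01) were near 0, and epicardial or mesothelial-like cells were at 0.21 and -0.06. The hypothesis was that the named genes ASNS, PSAT1 and WARS belong to a wider amino acid response, and the median of -0.31 of the synthetases not named by rank went with it at day 2. Many of these genes are known targets of ATF4.

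Some cardiac transcripts differed outside the cardiomyocyte-like cells. MYH7 was lower at day 2 and higher at day 4 in clusters 0 to 5, cluster 11 and endothelial-like cells, while NPPB had no common direction. In cluster 2 MYH7 was at 17.7 and 34.7 CPM at day 2 and 48.1 and 13.9 CPM at day 4. At day 4 in endothelial-like cells MYL2 was at 54.6 and 0.162 CPM, NPPB at 28.6 and 1.14 CPM and ANKRD1 at 28.3 and 1.95 CPM, and the number of cells behind these UMIs was not examined, whereas NPPB had ratios of -3.09 in cluster 1, -2.99 in cluster 5 and -1.20 in epicardial-like cells. The sarcomere list had medians of 0.55 in endothelial-like cells, 0.69 in cluster 2 and 0.55 in cluster 11 at day 4, but -0.23 in cluster 4, and was above 0 in 7 of 10 cell groups. Cryoinjured day 4 and non-cryoinjured day 2 also held the most cells of the low-UMI cluster 6 (326 and 352, beside 219 and 52 of the others), and free cardiac RNA was not tested as a source.

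Several clusters were found mostly in some libraries. Cluster 14, low in UMIs and led by SNORA76, COL7A1 and MYBPC3, held 126 cells of cryoinjured day 4 and 3, 5 and 0 cells of cryoinjured day 2, non-cryoinjured day 2 and non-cryoinjured day 4. Cluster 15 held 48 cells of cryoinjured day 4 and 59 of non-cryoinjured day 2 beside 11 and 10 of the others, with PRTN3 and AZU1 leading and a median of 1897 UMIs. The mixed cluster 13 had a median doublet score of 0.234.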
